A study of Mus musculus with 4 samples.

How the data were processed

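PolyA-selected RNA-seq was measured in 4 libraries of inflammation-experienced regulatory T cells (Treg), a CD4 T cell lineage that restrains immune responses. Per the labels, the cells came from a male adult mouse of 6 months of the Foxp3CreERT2 x Rosa26YFP strain. Such strains express an inducible Cre recombinase from the Foxp3 gene and carry a fluorescent reporter in Rosa26. The labels number the libraries as technical replicates 1 to 4 of biological replicate 1 from a single biosample, and they are called libraries 1 to 4 here. The labels also give Covaris shearing of the material and a size range of 100 to 300 bp. There was 1 group, so no comparison between conditions was made and no p-value measures one. Tests between libraries address only their spread, which may be technical. Tests on gene lists resample genes or random lists.

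Each library had 3 quantifications. The main one was a deposited gene table and transcript table with expected counts, TPM and FPKM, per the file headers, derived from a transcriptome alignment on mm10 with GENCODE M21, per the submitters' notes beside the files. The transcript table also held a percent of each gene's TPM per transcript, per the file headers. Those tables hold rows for transfer RNAs, spike-in controls and the phiX control besides the genes. The second set was a deposited table of estimated counts and TPM per transcript on the same annotation, made from the reads and an index, per the notes. The last was a deposited table of whole-number counts per gene on GENCODE M4, made from a genome alignment, per the notes. The programs, aligners and strand settings behind these files are not given in the sources used here. All coordinates are mm10, taken from the GENCODE M21 annotation, which matched the gene identifiers of the main tables.

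Rows outside the gene annotation were left out of library sizes and tests. They held 0.133%, 0.179%, 0.178% and 0.504% of the expected counts of libraries 1 to 4, nearly all of it in the phiX row. Of 422 genes on the 25 fixed lists, 420 were matched to the annotation. Where listed genes shared a symbol, the identifier with the highest mean count was used. For the M4 counts, 22195 genes were matched by identifier without its version. To set M4 counts beside TPM, they were divided by the mean effective length of the M21 table, with a minimum of 50 bp, and scaled over matched genes to the same total as TPM. The M4 and M21 tables were compared as log2(CPM + 1), with CPM over the matched genes, in genes of at least 1 TPM in both tables.

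List levels are the median over a list's genes of the mean TPM, with the SD over libraries of each library's median. List contrasts are differences of medians on the log2(TPM + 1) scale. They were tested with a two-sided permutation of list membership over genes with 100000 resamples, adjusted by Benjamini-Hochberg over the 10 contrasts. Genes are not independent replicates, so those p-values describe these lists in these libraries. Gene pairs were compared as log2 ratios of TPM + 0.1 with a two-sided exact sign-flip permutation test. With 4 libraries its smallest possible p is 0.13, so no pair can be called. A fold on a scale with a pseudocount understates differences of low genes.

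Expected counts were rounded to whole numbers before tests on counts. Whether a gene's share of counts differed between libraries was tested with a likelihood ratio chi-square of a Poisson model on TMM-scaled library sizes, in genes with a mean count of at least 10, with Benjamini-Hochberg adjustment at 0.05. The same tests were run for each pair of libraries. TMM factors and the biological coefficient of variation came from edgeR 4.0.16 with an intercept-only design, and its error is the jackknife SE over libraries. DESeq2 1.42.0 gave alternative size factors and dispersion, in R 4.3.3. The excess SD of a gene is its SD of log2 CPM over libraries after the variance of counting was subtracted. A list's median excess SD was set against 10000 random lists matched on mean count in 20 bins, two-sided, with Benjamini-Hochberg adjustment over lists with at least 3 tested genes. Genes of a random list were drawn independently, whereas members of a real list can vary together, so these p-values may be too small. Segment shares were tested with a chi-square test of homogeneity and carry Wilson 95% intervals for single libraries. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. GC content and length were taken from the leading transcript of each gene.

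The tests were first run on simulated data with known answers. In 13045 simulated genes with the real means and library sizes, the test between libraries found 72%, 84%, 100% and 100% of genes changed by 1.5, 2, 4 and 8-fold (50 genes each) and called 0.0623% of unchanged genes. The simulated counts held Poisson counting noise only, and genes were changed in a single library. Those rates therefore do not cover the further variation of the real libraries. The contrast test called 6 of 100 pairs of lists of normal random values drawn without a difference. Those values were not drawn from genes, so they do not cover lists with many zeros or with members that vary together.

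Depth in the M21 table ran from 6648385 to 9341328 expected counts per library. A count of 3, the limit that a count of 0 allows, is 0.323, 0.321, 0.322 and 0.451 CPM in libraries 1 to 4. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

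Lists, gene pairs, isoform genes, tests and most alternatives were fixed before the data were examined. The genes named are up to 6 members with the highest and 3 with the lowest mean TPM of each list, all members of the Treg core and sex check lists, the 15 most abundant nuclear protein-coding genes, all genes of the pairs and isoform list, the 10 genes of largest excess SD with a mean count of at least 50, each under its own identifier, the 6 most used Trbv and 4 most used Trav segments, and the 6 genes that differ most between the M21 and M4 tables. Immunoglobulin V segments, their families and B cell marker ratios were added after their values were seen. The alternatives covered other TPM minimums, FPKM, TPM over nuclear protein-coding genes, CPM without length correction, other pseudocounts, other scaling, other count filters, the other quantifications and each library left out in turn. Reads of the reporter and Cre sequences were not analysed here. Some genes that the rule names are not reported here.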

Results

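PolyA-selected RNA of inflammation-experienced Treg from an adult male mouse was sequenced in 4 libraries, which the labels give as technical replicates of 1 biological replicate. The labels name no other group, so the values describe this population and the spread between its libraries. The M21 gene tables held 9284432, 9341328, 9325636 and 6648385 expected counts in libraries 1 to 4. Library 4 was the shallowest. In each library, 13366 to 13867 genes reached 1 TPM, 13632 ± 246 (SD, n = 4), and 12008 genes did so in all 4 libraries, 9953 of them nuclear protein-coding. Mitochondrial genes took 3.50 ± 0.523% of counts (SD, n = 4) and the 10 most abundant genes of a library 8.31 ± 0.406%. The most abundant nuclear protein-coding genes were Actb, the cytoskeletal actin, at 16245 ± 3310 TPM, Rps19 at 10438 ± 834, Tmsb4x at 10100 ± 1064 and Eef1a1 at 9723 ± 691. Ribosomal protein genes, the class I antigen presentation genes B2m (7288 ± 829 TPM) and H2-K1 (5655 ± 276), and the ubiquitin gene Ubb (5340 ± 556) made up the rest of the leading 15. Their order depended on the quantification. In length-scaled M4 units Eef1a1 stood at 9985, Actb at 9094 and Tmsb4x at 4371. In the table made directly from the reads, TPM over coding genes was 27505 for Actb, 18452 for the ribosomal gene Rps27 and 14583 for Rps19. The 4 Y-linked genes measured were expressed, from Kdm5d at 26.7 ± 3.68 TPM to Eif2s3y at 147 ± 25.5, while Xist, the X-inactivation RNA of female cells, stood at 0.0900 ± 0.0845 TPM, or 0.0567 without library 4. The labels give a male mouse.

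The genes that mark Treg were expressed at a median of 181 ± 9.82 TPM (SD of library medians, n = 4), and 22 of the 24 measured members reached 10 TPM in all 4 libraries. The most abundant was Izumo1r, which encodes folate receptor 4 (ENSMUSG00000031933.17, chromosome 9, 14885814 to 14903949), at 1192 ± 242 TPM. The costimulatory receptor genes Tnfrsf4 and Tnfrsf18 stood at 551 ± 71.0 and 512 ± 59.3 TPM, Rgs1 at 548 ± 57.6 and Capg at 455 ± 69.4. Il2ra, the alpha chain of the interleukin-2 receptor (ENSMUSG00000026770.5, chromosome 2, 11642807 to 11693193), was at 204 ± 7.31 TPM and Ctla4, an inhibitory receptor gene (ENSMUSG00000026011.13, chromosome 1, 60887000 to 60915832), at 158 ± 19.0. Foxp3, the lineage-defining transcription factor (ENSMUSG00000039521.13, X chromosome, 7573644 to 7595245), was lower, at 27.8 ± 8.01 TPM, with 20.3, 21.7, 32.8 and 36.4 TPM in libraries 1 to 4. The Ikaros family gene Ikzf2, which encodes Helios (ENSMUSG00000025997.13, chromosome 1, 69531214 to 69687245), stood at 412 ± 124 TPM, Ikzf4 at 103 ± 13.1 and Ikzf3 at 55.4 ± 7.59. Tigit, Nt5e and Nrp1 stood at 299 ± 106, 244 ± 27.8 and 235 ± 30.4 TPM. Cd83, Itgae, Gpr83, Lrrc32, Entpd1, Socs2, Swap70 and Il2rb lay between 28.1 and 383 TPM. The lowest members were Nfil3 at 2.52 ± 1.25 and Plagl1 at 1.39 ± 0.701 TPM. From the M4 counts the list median was 109 ± 10.9 in length-scaled units, a change of over 1.5 times, and Foxp3 stood at 60.9 ± 18.5 against 105 ± 8.39 for Il2ra and 77.4 ± 18.9 for Ikzf2.

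**Figure D1:**
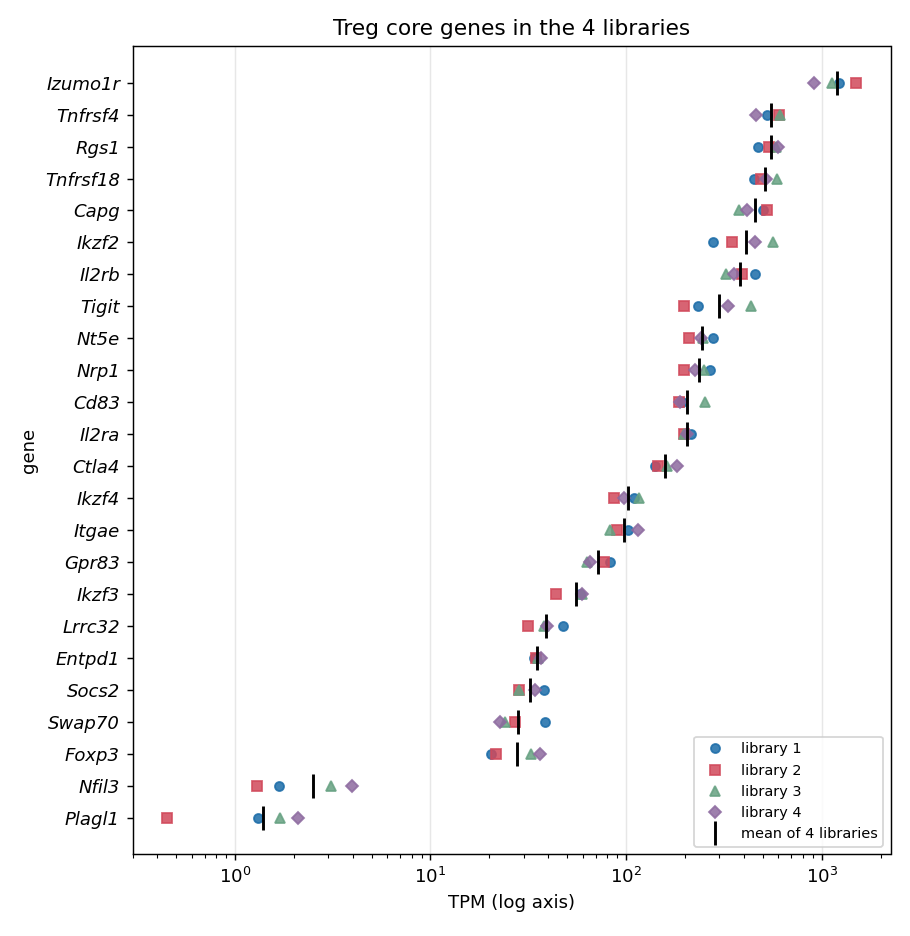
TPM of the 24 measured Treg core genes in each of the 4 libraries on a log axis, with the mean of the 4 libraries as a black bar. Izumo1r has the highest mean at 1192 TPM, and Foxp3 is near the bottom at 27.8 TPM with its libraries from 20.3 to 36.4.

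Genes of activated and tissue-repair Treg and genes of naive, resting T cells were both expressed. The effector list had a median of 51.3 ± 9.10 TPM (SD, n = 4), with 24 of 26 members at 1 TPM or more in all libraries. S100a11 led at 659 ± 96.0 TPM, followed by Lgals1 at 252 ± 49.7, the costimulatory receptor gene Icos at 242 ± 57.3, the inhibitory receptor gene Pdcd1 at 214 ± 44.6, Cst7 at 197 ± 27.8 and S100a6 at 166 ± 60.5. Il1rl1, which encodes the interleukin-33 receptor, was low at 3.69 ± 1.20 TPM, Havcr2 stood at 1.31 ± 0.336, and Areg, which encodes the tissue-repair factor amphiregulin, at 0.858 ± 0.668 with 0 counts in library 2. The anti-inflammatory cytokine gene Il10 was at 5.92 ± 2.51 TPM and Tgfb1 at 4.56 ± 0.692. Their order turned in the table made directly from the reads, with TPM over coding genes of 7.26 ± 2.79 for Il10 and 11.3 ± 2.72 for Tgfb1. The naive and resting list had a median of 84.8 ± 6.00 TPM, with all 20 members at 10 TPM or more in all libraries. Among its most abundant members were the transcription factor gene Tcf7 at 322 ± 12.6 TPM, the lymph node homing gene Ccr7 at 275 ± 56.8, Id3 at 262 ± 18.4, Foxp1 at 234 ± 19.3 and Ltb at 213 ± 71.3. Igfbp4, Dapl1 and Bach2 were its lowest members, at 14.1 ± 3.86, 13.7 ± 3.46 and 12.04 ± 1.39 TPM. The effector list lay 0.57 below the naive list on the log2 scale, with an SD of 0.39 over libraries, and the sign held in 3 of 4 libraries. A permutation test across genes gave an adjusted p of 0.655 (raw p 0.655), so the lists could not be told apart in level. From the M4 counts the naive list had a median of 51.8 ± 6.59 in length-scaled units, a change of over 1.5 times.

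T cell identity genes had the highest list median, 513 ± 25.0 TPM (SD, n = 4), and all 22 stood at 10 TPM or more in all 4 libraries. The receptor constant genes Trbc2, Trac and Trbc1 stood at 4047 ± 170, 3084 ± 228 and 2443 ± 128 TPM. The kinase gene Lck was at 1449 ± 151, Cd3g at 1395 ± 123 and Cd3e at 1385 ± 107 TPM. Thy1 and Bcl11b were the lowest members, at 128 ± 20.3 and 32.9 ± 3.76 TPM. Among helper lineage regulators, with a median of 29.6 ± 5.85 TPM, Id2 stood at 287 ± 32.6, Stat6 at 171 ± 26.9, Tox at 168 ± 38.1, Stat4 at 129 ± 10.9 and Gata3, the regulator of type 2 helper cells, at 96.5 ± 12.01. The follicular regulator Bcl6 was at 19.5 ± 4.28 TPM and the type 1 regulator Tbx21 at 2.26 ± 0.801. Ahr stood at 5.07 ± 1.72 and Eomes at 0.178 ± 0.147 TPM. Effector cytokine genes were near the floor: 3 of 14 reached 1 TPM in all libraries, namely Tnf at 17.9 ± 2.60, Il4 at 14.3 ± 5.77 and Ifng at 9.41 ± 0.583 TPM. Il21 was at 3.66 ± 2.18, Il2 at 1.02 ± 0.409 and Il12a at 0.468 ± 0.250 TPM. Il3, Il9 and Il22 had 0 counts in all 4 libraries, which allows up to 0.451 CPM in the shallowest.

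Chemokine receptor and homing genes had a median of 98.2 ± 6.08 TPM (SD, n = 4), and all 20 reached 1 TPM in all 4 libraries. Adhesion genes led them, with the integrin gene Itgb2 at 452 ± 118, the selectin ligand gene Selplg at 395 ± 62.5, and the integrin genes Itgb7 at 286 ± 23.3, Itga4 at 212 ± 24.6 and Itgal at 204 ± 30.02 TPM, and the activation marker Cd69 at 186 ± 22.1. Ccr4 and Cxcr4 were among the lowest, at 16.0 ± 3.30 and 6.96 ± 2.68 TPM. Cytokine receptor and signalling genes had a median of 31.7 ± 4.83 TPM. They were led by the shared gamma chain Il2rg at 1434 ± 296, Il27ra at 266 ± 12.9, Jak1 at 265 ± 51.0 and Ifngr1 at 206 ± 48.9, while Il18rap, Socs1 and Il12rb2 stood at 11.7 ± 2.15, 2.22 ± 0.751 and 0.300 ± 0.302. Interferon response genes had a median of 55.4 ± 10.1 TPM, led by Ifi27l2a at 662 ± 67.5, Igtp at 346 ± 72.4 and Iigp1 at 222 ± 26.2. Proliferation genes had a median of 14.5 ± 2.27 TPM, with Hmgb2 at 181 ± 32.7, Pcna at 110 ± 9.84 and Stmn1 at 68.5 ± 19.1, and the mitotic genes Cdc20, Ccna2 and Bub1 lowest at 2.95 ± 0.711, 2.15 ± 0.823 and 1.26 ± 0.493. Immediate early and stress genes had a median of 18.0 ± 4.21 TPM. Nfkbia, Btg2, Klf6 and Zfp36 led them at 363 ± 93.1, 223 ± 46.1, 159 ± 19.5 and 146 ± 15.9, and Atf3 was at 0.302 ± 0.433. Atf3 and Il12rb2 were highest in library 1, at 0.94 and 0.73 TPM, and their means without it were 0.0900 and 0.157 TPM.

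Among metabolic genes, the glycolysis list had a median of 85.1 ± 18.6 TPM (SD, n = 4) and the oxidative phosphorylation and fatty acid oxidation list 177 ± 3.66. Aldoa, Ldha, Pkm and Eno1 stood at 808 ± 145, 687 ± 32.9, 676 ± 139 and 517 ± 152 TPM, and the inducible glycolytic genes Hk2 and Slc16a3 at 2.32 ± 0.765 and 1.69 ± 0.964. Cox4i1 stood at 858 ± 30.5, Uqcrh at 698 ± 54.3 and Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, at 20.2 ± 5.76 TPM. Apoptosis regulators had a median of 42.8 ± 5.03 TPM, with Bcl2a1b at 247 ± 47.0, Cflar at 148 ± 14.8 and the survival gene Bcl2 at 125 ± 14.5, and the death-promoting Bbc3 at 0.215 ± 0.195. Bcl2a1b has near-identical family copies, so its share of reads is uncertain. Epigenetic regulators had a median of 25.0 ± 5.58 TPM. Hdac1 led them at 208 ± 23.7, the maintenance DNA methyltransferase gene Dnmt1 stood at 35.5 ± 7.84 and the de novo methyltransferase gene Dnmt3b at 3.57 ± 0.731.

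**Figure D2:**
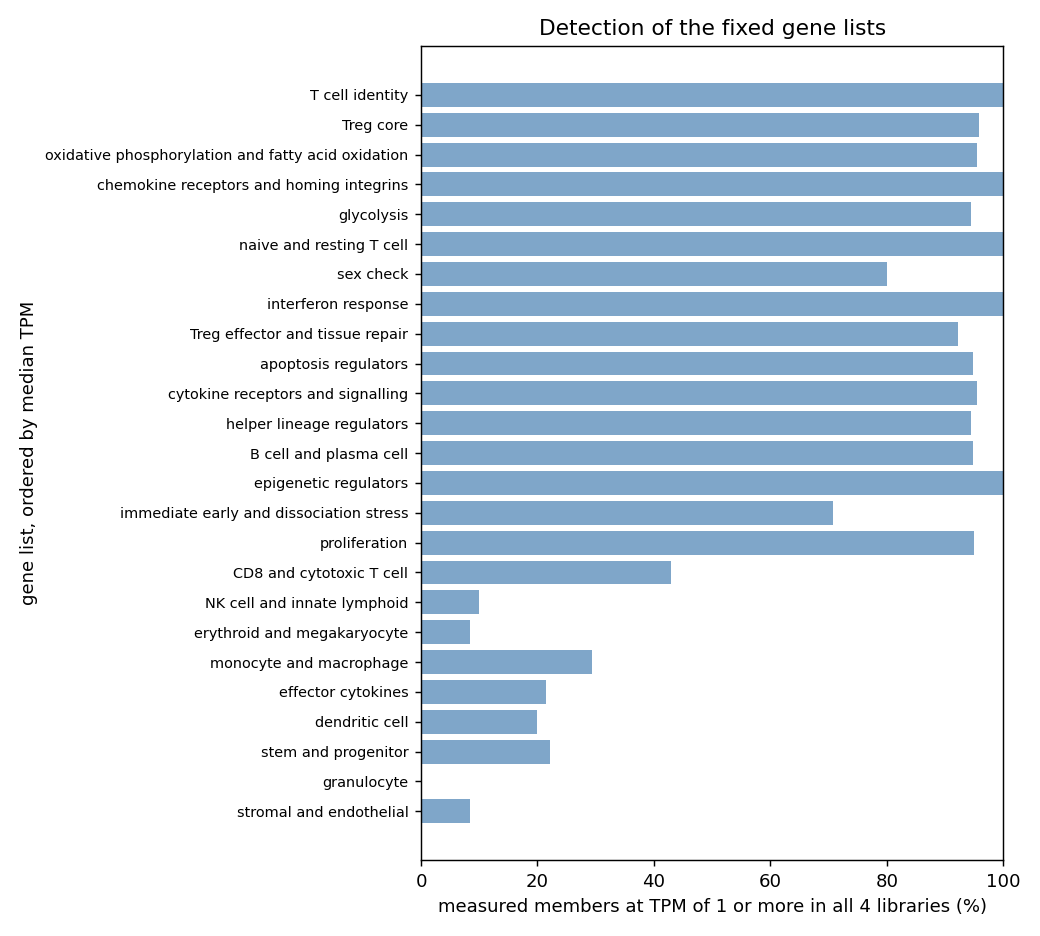
Percent of the measured members of each of the 25 fixed gene lists that reached 1 TPM in all 4 libraries, with lists ordered by their median TPM. All 22 T cell identity genes and 23 of 24 Treg core genes did so, against 0 of 14 granulocyte genes.

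The lists of marker genes of other cell types had lower medians than the Treg core list. Single markers such as Ighm and Cd74 exceeded the Treg core median. By counts, Ighm was 28.5 to 156 times the B cell gene Cd79a in the 4 libraries, so its level cannot be read as an amount of B cells. The difference of medians between Treg core and each of the 9 other lists ran from 3.04 to 7.43 on the log2(TPM + 1) scale, and had one sign in all 4 libraries. In permutation tests across genes all 9 contrasts passed the adjusted threshold. The least separated was the B cell and plasma cell list, 3.04 ± 0.648 (SD, n = 4) below Treg core, with an adjusted p of 0.00121 by permutation (raw p 0.00109). Its median was 25.3 ± 10.5 TPM and 18 of its 19 members reached 1 TPM in all libraries. Ighm, the heavy chain of immunoglobulin M, stood at 1016 ± 242 TPM, the class II chaperone gene Cd74 at 835 ± 202, the light chain gene Igkc at 717 ± 367, H2-Aa at 86.5 ± 46.1, Cd79b at 79.1 ± 14.8 and the B lineage factor Pax5 at 2.54 ± 2.27, or 1.47 without library 1. The CD8 and cytotoxic list had a median of 2.10 ± 1.30 TPM, with Cd8b1 at 11.7 ± 2.05 and Cd8a at 2.10 ± 1.64. The natural killer and innate lymphoid list had a median of 0.700 ± 0.282, led by Tyrobp at 4.64 ± 4.06 and Fcer1g at 4.61 ± 3.91, which library 1 raised, as they stood at 2.64 and 2.91 without it. The monocyte and macrophage list had a median of 0.558 ± 0.221, with the protease gene Ctss an exception at 439 ± 27.3 TPM and Apoe and Lyz2 at 11.9 ± 7.28 and 10.9 ± 8.54, the latter 7.23 without library 1. The dendritic cell list had a median of 0.293 ± 0.274, and its highest member Bst2, which is also on the interferon list, stood at 70.4 ± 32.4. The granulocyte list had a median of 0.0800 TPM, or 0.0117 without library 1, and no member reached 1 TPM in all libraries. S100a8 stood at 1.43 ± 1.603, or 0.723 without library 1. The stem and progenitor list had a median of 0.110 ± 0.0486 with Ly6a at 335 ± 46.3, and the stromal and endothelial list 0.0425 ± 0.0191 with Pecam1 at 88.2 ± 13.8. These last medians fell to 0.0467 without library 3 and 0.0133 without library 2. Ctss, Bst2, Ly6a and Pecam1 are also known in T cells.

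The erythroid and megakaryocyte list had a median of 0.629 ± 0.580 TPM (SD, n = 4), and 1.53 TPM in library 1 against 0.395, 0.450 and 0.300 in the others. Its haemoglobin gene Hba-a2 stood at 396 TPM in library 1 against 0.670, 14.4 and 2.68 in libraries 2 to 4, and Hbb-bs at 344 against 0.730, 13.7 and 9.18. Hba-a1 and Hba-a2 encode near-identical transcripts, so the split of reads between them is uncertain. Alas2, the erythroid enzyme of haem synthesis, had 55, 8, 11 and 8 expected counts.

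Ratios of gene pairs fixed beforehand placed Foxp3 above Tbx21 by 3.60 ± 0.40 and below Gata3 by 1.83 ± 0.51 on the log2 scale (SD, n = 4). Cd4 exceeded Cd8a by 7.89 ± 1.29, Bcl2 exceeded the death-promoting Bcl2l11 by 3.18 ± 0.28 and Ccr7 exceeded Cxcr3 by 0.87 ± 0.22. Il2ra exceeded Il7r by 0.72 ± 0.11, Ikzf2 exceeded Ikzf4 by 1.96 ± 0.42, Trbc2 exceeded Trbc1 by 0.73 ± 0.03 and Dnmt1 exceeded Dnmt3a by 1.10 ± 0.38. These were among the 10 of the 20 pairs that had one sign in all 4 libraries and a ratio over 2 SD. In the exact sign-flip permutation test no pair could reach 0.05, since the smallest p it can give with 4 libraries is 0.13. From the M4 counts the order of Ikzf2 and Ikzf4 turned, to -0.35 ± 0.31, as did that of Il2ra and Il7r, to -0.15 ± 0.14. They also moved Foxp3 over Tbx21 to 4.57 ± 0.50, Foxp3 over Gata3 to -0.72 ± 0.62, Bcl2 over Bcl2l11 to 4.46 ± 0.24 and Dnmt1 over Dnmt3a to 2.99 ± 0.58. The last fell to 0.24 ± 0.67 in the table made directly from the reads and to 0.36 ± 0.33 without length correction, where Foxp3 over Tbx21 was 2.97 ± 0.39 and Foxp3 over Gata3 -2.88 ± 0.51. With a pseudocount of 1, Cd4 over Cd8a was 7.18 ± 0.88. The remaining pairs lay within 2 SD of 0, among them Tcf7 over Id2 at 0.17 ± 0.15, Bach2 over Prdm1 at 0.32 ± 0.25 and Stat5b over Stat5a at 0.02 ± 0.07.

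The leading transcript was identified for 18 genes chosen beforehand. Foxp3-207 held 81.5 ± 7.03% of the Foxp3 TPM (SD, n = 4), Ctla4-201 98.3 ± 1.24% and Tcf7-201 98.5 ± 0.380%. Ptprc-203 held 40.7 ± 2.06% of Ptprc, which encodes the CD45 phosphatase, and Cd44-207 51.0 ± 3.74% of Cd44. Ikzf2-205 held 61.7 ± 7.09% of the Ikzf2 TPM but 27.9% of its expected counts. Bach2-207 held 33.7 ± 17.2%, with the largest SD in the main table, against an SD of 7.10 in the table made directly from the reads. By expected counts Bach2-207 held 65.2% and Icos-202 85.6%, against 55.4 ± 2.64% of the Icos TPM. In the table made directly from the reads, the leading transcript was the same in 17 of the 18 genes. The exception was Tnfrsf18, where Tnfrsf18-203 led with 54.1% in place of Tnfrsf18-202, which had 33.8% there and 79.7 ± 1.89% in the main table.

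T cell receptor beta V segments were used in similar shares in the 4 libraries, from 3829 to 5849 reads each. Trbv3 led in all of them, with 11.2 ± 1.04% (SD, n = 4). It held 9.93% of library 2 (Wilson 95% interval 9.19 to 10.7%) and 12.5% of library 3 (11.6 to 13.4%). Trbv19, Trbv13-2, Trbv5, Trbv16 and Trbv13-3 followed with 9.48 ± 1.08, 8.73 ± 0.785, 7.48 ± 0.460, 7.16 ± 0.246 and 6.53 ± 0.535%. The shares nevertheless differed beyond counting error, with a chi-square of 233 on 63 degrees of freedom (p = 2.4e-21, adjusted p = 2.4e-21 over 4 segment classes) and a Cramér's V of 0.062 over 22 segments. Of the alpha segments, Trav7-4 led with 5.36 ± 0.542%, before Trav12n-3 at 3.20 ± 0.617%, Trav4-4-dv10 at 3.14 ± 0.810% and Trav9-1 at 3.00 ± 0.475%. Cramér's V was 0.171 over 104 Trav segments (chi-square 1038, p = 1.3e-79, adjusted p = 1.8e-79). Many Trav segments have near-identical copies, and the split of reads between these is uncertain.

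**Figure D3:**
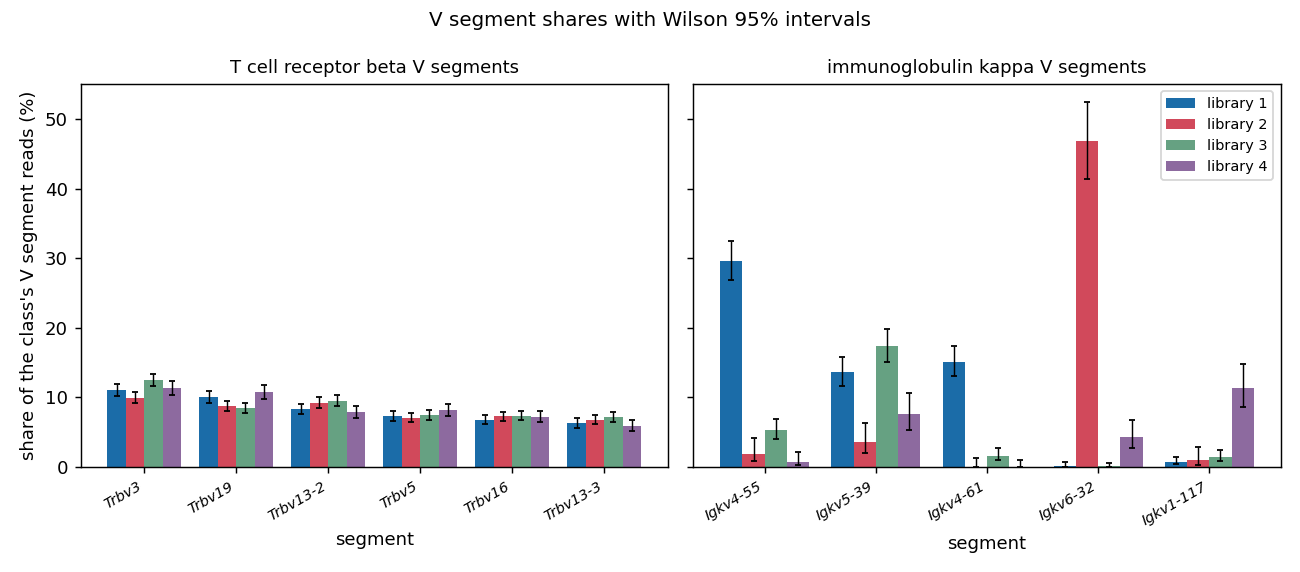
Share of each class's V segment reads, in percent, for the 6 most used T cell receptor beta segments on the left and 5 immunoglobulin kappa segments on the right, with a bar for each of the 4 libraries and Wilson 95% intervals. Trbv3 holds 9.93 to 12.5% in the libraries, while Igkv6-32 holds 46.9% in library 2 and 0.104% in library 3.

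The libraries differed from one another by more than counting noise. Of 13045 tested genes with a mean count of at least 10, 8945 (68.6%) had shares of counts that differed between the 4 libraries, and 2056 of these spanned at least 2-fold. The common biological coefficient of variation was 21.3 ± 2.03% (jackknife SE). It was 12.2% for libraries 3 and 4 and 21.2 to 23.6% for the other 5 pairs, and 20.4% of genes differed between libraries 3 and 4 against 39.9 to 44.2% in the other pairs. No pair of libraries stood within sampling noise, so none was merged, and n is the number of technical libraries of 1 biological replicate. Of 267 genes taken by the naming rule, 49 had a mean TPM that moved by over 1.5 times with a library left out, 27 of them most without library 1, and 21 of the 49 had a mean of at least 1 TPM. Without library 1, which held the haemoglobin transcripts, 7049 genes differed. T cell genes took part: Cd4 stood at 410 ± 111 TPM, and Ikzf2 ranged from 279 TPM in library 1 to 562 in library 3.

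**Figure D4:**
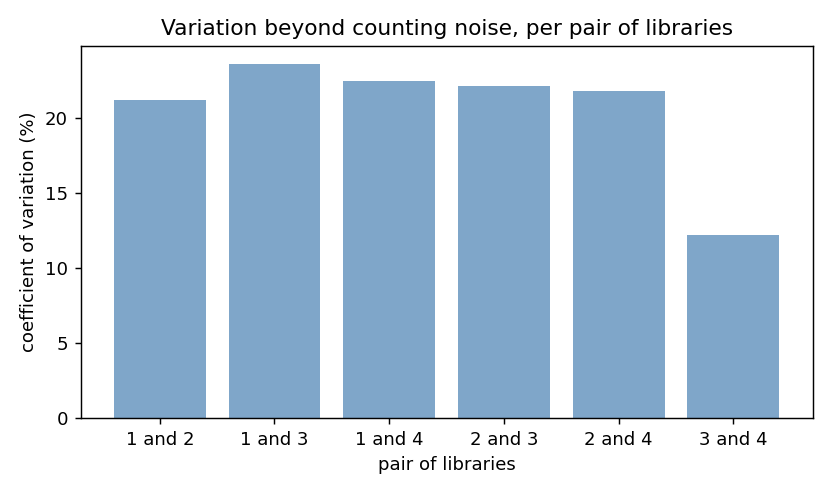
Biological coefficient of variation, in percent, of each of the 6 pairs of libraries, estimated by edgeR from genes with a mean count of at least 10. Libraries 3 and 4 show 12.2%, and the other pairs 21.2 to 23.6%.

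Among the fixed lists, 5 varied between libraries by more than random lists matched on mean count. They were the erythroid and megakaryocyte list (median excess SD 3.52 log2 against 0.24 for matched lists, adjusted p = 0.0015 by resampling of random lists), the B cell and plasma cell list (0.80 against 0.20, adjusted p = 0.0015), the immediate early and stress list (0.37 against 0.21, adjusted p = 0.0015), the chemokine receptor and homing list (0.30 against 0.18, adjusted p = 0.0055) and the monocyte and macrophage list (0.74 against 0.26, adjusted p = 0.0055). The first 3 p-values rest on the smallest raw value that 10000 random lists can give, 0.0002. All 5 may be too small, since members such as the haemoglobin genes vary together and random lists are drawn gene by gene. Without library 3 only the B cell and erythroid lists kept a call, and the monocyte list also lost it without library 1. Treg core genes had a median excess SD of 0.20 against 0.18, and T cell identity genes 0.16 against 0.17. Of the 24 Treg core genes tested, 23 differed between libraries, and 23 did so when adjusted over the list alone. For T cell identity it was 22 of 22 by either count, and for the effector list 23 of 25 by either count.

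The 10 genes of largest excess SD were Rps13-ps2, Rpl7a-ps11, Ighg1, Zc3h11a, Gm45837, Gm26699, Trav7d-2, Gm6565, Hba-a1 and Nnt, and each had a count of 0 in at least 1 library of the main table. Most of them share sequence or position with another gene, so their counts are uncertain. The pseudogene Rps13-ps2 (ENSMUSG00000069972.6, chromosome 7, 88530446 to 88530898) had 1450, 1727, 0 and 0 counts, and 783, 1002, 211 and 288 TPM in the table made directly from the reads. Nnt is listed under 2 identifiers, and the variable one (ENSMUSG00000116207.1, chromosome 13, 119335528 to 119408952) had 259 counts in library 3 and 0 in the others, against 5.20 to 7.72 TPM in all 4 libraries of the direct table. For 3 of the 10 genes the direct TPM stayed within 2-fold over the 4 libraries. Ighg1, the heavy chain of immunoglobulin G1, had 1070, 0, 26 and 9 counts, and 1967, 1, 48 and 6 in the M4 table.

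The M21 and M4 gene tables ranked genes alike within a library but differed for particular genes. Across 9847 to 10143 genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.905 ± 0.006 (SD, n = 4) and Spearman's rho 0.888 to 0.904. Between 12.9 and 14.8% of these genes differed over 2-fold. Among genes with a mean count of at least 100, those that differed most included mt-Atp6, mt-Co2, mt-Co3, Hnrnpu and Nme2, which had 0 to 8 counts per library in the M4 table and 1067 or more in M21. Of the coding genes named by the rule at 1 TPM or more, 107 of 213 moved by over 1.5 times in length-scaled M4 values. In the table made directly from the reads, 12 of 215 did. These counts have unlike bases and cannot be set side by side. M4 values, scaled over matched genes alone, were divided by TPM over all genes, which raises their ratios. Direct values over coding genes were divided by TPM over coding genes. Treg genes differed as well. Foxp3 stood at 35.8 CPM in M21 and 71.5 in M4, Il2ra at 599 and 283, and Ikzf2 at 1394 and 241, whereas Ctla4 stood at 241 and 196. The strain carries a modified Foxp3 allele, per the labels, and neither table states how it was handled.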

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

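The tests of explanations in this part were chosen after the results were seen, except the count of lists highest in library 1. Of 265 values tested for a library far from the other 3, 26 stood out, or 9.81%. Chance gives about 1 in 20 for normal values that were not selected. The 265 included genes named for their large spread between libraries, such as Ighg1 and Nnt, so part of the excess is built in. Library 1 held 13 of them, library 2 held 3, library 3 held 5 and library 4 held 5. These values are not independent of one another.

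Haemoglobin transcripts were far higher in library 1, where Hba-a2 stood at 396 TPM, Hbb-bs at 344, Hba-a1 at 220 and Hbb-bt at 100.2, and the median of the erythroid list was 1.53 TPM. A lower T cell share in library 1 would raise markers of all other cell types, and it stays open. The erythroid list, whose 6 tested genes include the 4 haemoglobin genes, rose by 4.04 more (log2) than the B cell list (bootstrap 95% interval 2.19 to 4.72). That test cannot decide, since its outcome was set by the haemoglobin genes that prompted it. It shows only that these lists did not rise alike. An earlier test, whose bounds were set before its value was seen, was undecided. Of the 7 lists with enough counts, 5 were highest in library 1. A lower share asked for all 9 and its absence for 3 or fewer. With 7 lists tested, the count of 9 could not be reached, so that test could not have argued for a lower share. Red-cell RNA in library 1 is a candidate explanation, as the CPM of Alas2 was 5.52 times the mean of the others (exact 95% interval 3.50 to 9.30), and its M4 counts were 129, 21, 52 and 31. By TPM, which depends on the isoforms assigned, Alas2 stood at 4.57, 2.15, 3.62 and 2.80. In the table made directly from the reads, Alas2 had 5.21 ± 0.820 TPM over coding genes. That spread between libraries is too small for a rise of 5.52 times in library 1. A sort for T cells, if one was used, would deplete red cells but need not remove all of their RNA.

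The share of counts in the phiX control, which sequencing runs add as a standard, was 0.133%, 0.179%, 0.178% and 0.504% in libraries 1 to 4, with Wilson 95% intervals of 0.131 to 0.135% and 0.499 to 0.510% for the lowest and the highest. It lies outside the measurements of the report, above the limit that a count of 0 allows, and library 4 stood far from the rest. Library 4 also stood apart in depth, with 6648385 expected counts in the M21 table and 6724013 counts in the M4 table.

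In library 1, Ighg1 stood out at 163 TPM, Apoe at 22.8, Gzma at 3.39 and S100a9 at 5.35. The signalling genes Stat5a and Stat5b were at 42.8 and 41.9 TPM in library 1, and Dnmt1 at 47.2. The median of the stem and progenitor list was 0 TPM there. In library 2, Ikzf3 was at 44.0 TPM, Epcam at 0.730 and Gm26699 at 17.3. In library 3, Cd83 stood at 253 TPM, Tox at 225, Tnf at 21.8, Eed at 69.0 and Nnt, under the identifier given in the report, at 10.7. In library 4, Lgals1 stood at 326 TPM and Bach2 at 14.1.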

How the results depend on the processing

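Alternatives by the direct transcript table, a 2-fold minimum, GC correction and those for single genes were chosen after the data were seen. The median TPM of the Treg core, effector and naive lists became 146, 41.5 and 68.3 with FPKM, and 228, 65.0 and 107 over nuclear protein-coding genes, a rescaling by construction. From M4 counts it was 109 for Treg core and 51.8 for the naive list, and in the direct table it became 64.9 for the effector and 98.6 for the naive list. The cause was not tested for these and the pairs below. The 9 contrasts with other cell types kept their direction and call in all alternatives run, and the effector against naive contrast stayed uncalled. Genes at 1 TPM in all libraries numbered 9853 to 13207 and the coefficient of variation was 19.6 to 22.5%. The 8945 differing genes became 2056 with a 2-fold minimum, 6862 to 9615 under other settings, 8380 with GC content and length removed and 7049 to 8154 with a library left out. The number of lists that varied was 8 instead of 5 with library totals, 7 with a mean count of at least 50, and 2 to 8 with a library left out, lowest without library 3. Of the leading isoform shares under alternatives, 26 moved by over 1 SD and 82 did not. Correlation of tables rose to 0.961 over all matched genes, which adds genes unexpressed in both.

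Pair ratios changed sign in 13 cases, and only Ikzf2 over Ikzf4 and Il2ra over Il7r had exceeded 2 SD. Without length correction Foxp3 over Bcl6 became -0.72, Tgfb1 over Il10 0.49, Klf2 over Klrg1 0.022 and Tnfrsf18 over Tnfrsf4 0.22. From M4 counts Ikzf2 over Ikzf4 became -0.35, Il2ra over Il7r -0.15, Tcf7 over Id2 -0.45, Bach2 over Prdm1 -0.33 and Stat5b over Stat5a -0.60. The direct table gave -0.0070 for Tcf7 over Id2, 0.68 for Tgfb1 over Il10 and 0.13 for Klf2 over Klrg1. With a library left out, Stat5b over Stat5a ranged from -0.015 to 0.038. Genes near the floor, such as most effector cytokines, are limited by depth.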

Other observations

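The tests of explanations in this part were chosen after the results were seen, except the share of gene scores explained by GC content and length and the count of other-type genes among the largest scores. Immunoglobulin transcripts were present in every library, and B cell and antibody-secreting markers did not move together. The ratio of H2-Aa to Cd79a, both B cell genes, was 2.99, 2.99, 3.09 and 2.21 in libraries 1 to 4 (chi-square adjusted p = 0.0287). In contrast the ratio of Igkc to Cd79a was 8.15, 3.67, 33.5 and 5.54 (chi-square 340 on counts, adjusted p = 2.1e-72), and that of Jchain, which encodes the joining chain of secreted antibodies, 1.77, 1.42, 8.47 and 1.29. Xbp1, a regulator of secretory cells that other cells also express, had ratios of 1.47, 0.354, 5.45 and 1.35. The 8 ratios tested were picked after their values were seen.

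The V segments of immunoglobulin differed between libraries far more than those of the T cell receptor. Among kappa segments Igkv6-32 held 46.9% of 309 reads in library 2 (Wilson 95% interval 41.4 to 52.5%) but 0.189%, 0.104% and 4.29% in libraries 1, 3 and 4, and Igkv4-55 held 29.6% of 1060 reads in library 1. Among heavy chain segments the leader was Ighv1-75 in library 1 (31.6%), Ighv1-61 in library 2 (41.9%), Ighv5-4 in library 3 (27.7%) and Ighv7-3 in library 4 (12.7%).

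A division of 1 RNA pool between the libraries is argued against, since such a pool would give Igkv segments the spread of other genes of like count, amplification included, but the median excess SD of 17 Igkv segments was 1.65 (log2) against 0.32 for random lists matched on mean count, none of 10000 of which reached it (Cramér's V 0.648). Sharing of reads between near-identical segments is argued against as the whole cause, since Cramér's V was still 0.448 with counts summed over 18 segment families, and the Igkv6 family held 53.1% in library 2 against 3.77%, 7.83% and 9.09% in libraries 1, 3 and 4. A small number of antibody-producing cells, different in each library, is a candidate explanation that was not tested. The labels call the libraries technical replicates, and how the material was divided is not given in the sources used here. Cells of other types count here among the technical explanations, and no biological explanation was tested, as the design holds 1 group.

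Libraries 3 and 4 lay closer together than the other pairs. The leading principal component of 9840 genes placed libraries 1 to 4 at 22.9, 18.2, -19.5 and -21.7. It held 47.8% of the variance, against 34.5% for the second component. Rps13-ps2, Gm6565 and Gm45837, also among the 10 genes of largest excess SD, had some of the largest scores on the leading component. GC content and length explained 11.6% of its gene scores, between the bounds set before the value was seen (over 50% for a cause, under 10% against it), but with their trend removed the smallest SD of log2 ratios among the other pairs was still 1.33 times that of libraries 3 and 4 (bootstrap 95% interval 1.16 to 1.48, and 1.37 before), which argues against that trend as the whole cause. Depth is argued against, since the closest pair held the shallowest library, 4, while libraries 1 and 2, of like depth, had a coefficient of variation 8.97 percentage points higher. Cells of the 9 other types stay open after 4 tests. The one fixed beforehand was undecided, with 10 of the 100 largest scores in their markers or immunoglobulin genes, where fewer than 10 would argue against them. The 2 later counts of T cell genes on each side of the component (15 and 6, 21 and 12) had no bound. The last was a difference of 0.31 in the median absolute log2 ratio of 47 markers, larger between libraries 3 and 4 than between 2 and 4. The pair of libraries 2 and 4 was picked after the values were seen (bootstrap 95% interval 0.01 to 0.87, but -0.07 to 0.91 when widened for the 5 pairs it was picked from). The median was 0.90 for libraries 3 and 4, above that of 1 and 4 (0.65) and of 1 and 2 (0.75). It was below that of 2 and 3 (0.97) and of 1 and 3 (1.67). Also open are a difference in library preparation or in the T cells themselves, neither of which was tested, and admixture of other CD4 T cells, for which no list specific to non-regulatory cells was fixed and the naive list's median deviations of 0.03, 0.17, -0.22 and -0.05 (log2) in libraries 1 to 4 do not decide.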
